A study of Mus musculus with 170 samples.

How the data were processed

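RNA was sequenced from cell types sorted by flow cytometry from mice of 2 ages, with cells of 5 animals pooled per library, per the labels' protocols. Libraries were made from the 3' ends of poly(A) RNA, with a sample index of 8 bp and a unique molecular identifier of 10 bp, per the labels' protocols. Whether identifiers were used to remove copies is not given in the sources used here. The submitters' processing notes name sabre 80faf94, STAR, featureCounts 2.0.1 and the builds GRCm38.p6 and mm10, with no order or settings. The values used were the counts per gene as deposited by the authors in a table of 55484 genes and 170 libraries. They are whole numbers with no normalization.

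Groups were cell type and age as given in the sample titles. For B cells old replicate 1 other tags named visceral fat adipocytes, and the title was followed. Of the genes 4951 had no count in any library and 37 mitochondrial genes had 0 counts throughout, so the list of mitochondrially encoded mRNAs was void. Another 26 entries had names turned into dates (0.202% of counts). Names of 53362 genes were found in GENCODE M21, which gave coordinates on GRCm38 and held 99.1% of counts. Among 249 replicate pairs 0 were identical. The chi-square per degree of freedom between replicates was at least 2.26, and their median Spearman correlation 0.935.

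Total counts ran from 566292 to 16231229 per library. Each cell type was tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, TMM scaling) in R 4.3.3, old against young, after filterByExpr with a minimum count of 10 and a minimum total of 15. Adjusted p is Benjamini-Hochberg within a comparison, with a threshold of 0.05. A shared change was fitted over all cell types with terms for cell type and age, and CD4 and CD8 memory and naive cells were compared through an interaction term. Named genes were those past the threshold with at least 20 CPM in the higher group and no overlap of the libraries, taking the 5 with the highest and the 5 with the lowest log2 fold change per cell type. Sex-linked genes (Xist, Tsix and chromosome Y), unnamed models, pseudogenes, antisense genes and immunoglobulin or T cell receptor segments were left out. Shared genes were the 12 highest and 12 lowest with the same sign in at least 18 cell types and measured in at least 20. In the interactions the 5 highest and 5 lowest were taken with no rule on overlap. Of a called list up to 4 members past the threshold with the lowest adjusted p were named. Recurrent genes were the 10 per direction called in most cell types. Some genes that met these rules are not reported here.

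The 19 gene lists and 29 lists of marker genes of other cell types were tested within cell types with fry and, with an estimated correlation, with camera (limma 3.58.1). Fry tests whether the genes of a list move one way on balance and does not compare a list with other genes. Of 243 marker list tests 24 passed with fry, 11 higher and 13 lower in 12 cell types, and 0 passed with camera. List means and library properties were compared over cell types by two-sided sign-flip permutation with 100000 resamples, and correlations of fold changes by permuting tissue labels. The comparisons, lists, rules for names and other settings to try were fixed, apart from those said to be chosen later, before the data were examined.

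Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, leaving out each library, limma on log2 fold changes per cell type or tissue with or without genes missing in some, correlations without the spleen T cell subsets, medians over libraries of the immunoglobulin share, and estimated correlations. Replicate numbers were taken to pair libraries where every pair of deviations correlated above 0.1 with at least 3 pairs, which held for brain endothelial cells (0.117 to 0.286). The number comes from the titles. Counts of genes were called the same within a factor of 1.5.

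The tests were tried on simulated counts with 200 changed genes per comparison. Within cell types the share of 2-fold changes recovered had a median of 45.9%, and that of 4-fold changes ran from 70.4% to 98.9%. The highest share of false calls was 10.5%. The CD4 interaction recovered 3.13% of 2-fold and 64.1% of 4-fold changes and the CD8 interaction 5.94% and 53.9%. Coordinates and fold changes of genes with near-identical copies are uncertain where reads were shared.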

Results

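Gene expression was measured by RNA sequencing in cells sorted from young mice, aged 2 months, and old mice, aged 22 to 24 months. The 170 libraries, 84 young and 86 old, covered 23 cell types from 12 tissues, with 2 to 7 libraries per cell type and age. Each library pooled cells of 5 animals, so a p-value here reflects the spread between pools. No test here separated age from cohort or genotype. Levels are normalised counts (CPM) with the SD between libraries, and log2 fold changes are old minus young with their standard error, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Coordinates refer to GRCm38, and the named genes are protein coding unless stated.

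A first question was which genes differed with age within each cell type. Thymic epithelial cells had the highest count of changed genes, 1531 of 13428 tested, followed by adipocytes with 1397, haematopoietic stem cells (HSC) with 1199, CD4 naive T cells with 1135 and kidney tubular cells with 1039. Over the cell types there were 9448 changes in 6082 distinct genes. In data simulated at the depth of each cell type, recovery of 2-fold changes ran from 6.32% in neurons to 73.1% in B cells, so the counts cannot be ranked as sizes of an age effect.

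**Figure D1:**
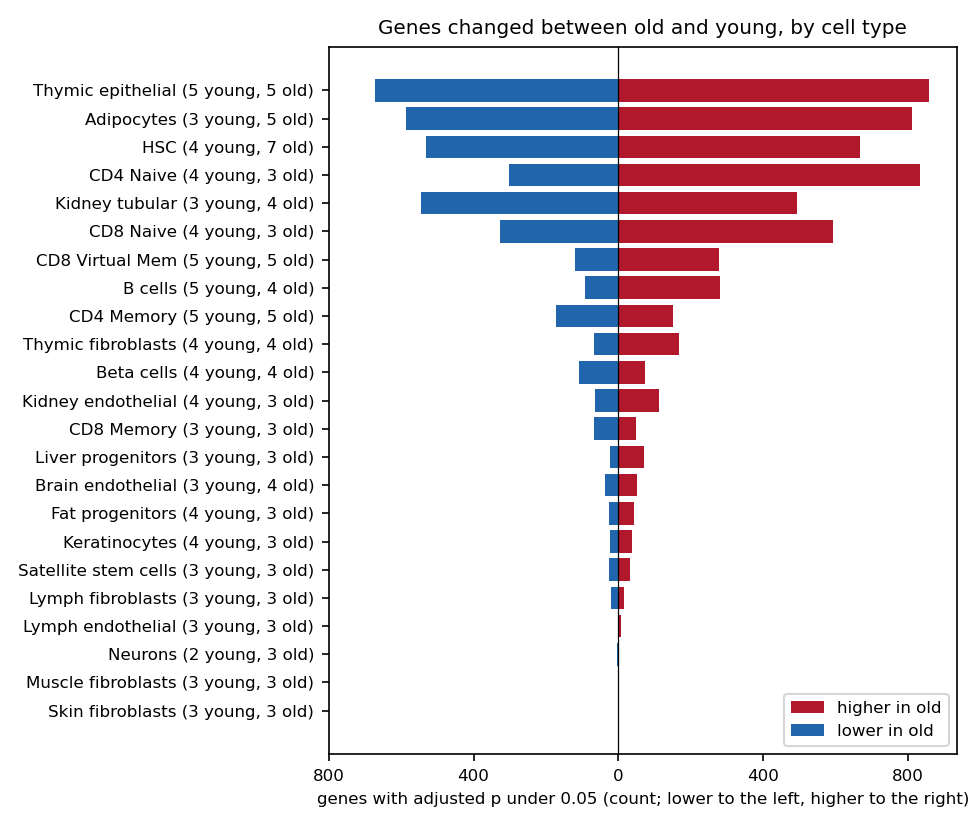
Genes past an adjusted p of 0.05 in each cell type, old against young, with counts of genes higher in old animals to the right of 0 and lower ones to the left on a linear axis. Thymic epithelial cells had 860 higher and 671 lower genes, and skin fibroblasts had 0.

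A second question was whether the cell types shared any change. Ide, for insulin-degrading enzyme (chr 19, 37268743 to 37337852), was higher in old animals in 23 of 23 cell types and passed in 10. Its mean log2 fold change was 0.82 ± 0.31 (SD over cell types), and a cohort or genotype cause stays open. H2-Q7, a class I histocompatibility gene (chr 17, 35439155 to 35443773), had a mean of 0.96 ± 0.77 and was higher in 20 of 21 cell types. Casp4, an inflammatory caspase (chr 9, 5308828 to 5336783), rose by 1.14 ± 1.30 with 19 of 21 higher, and S100a6, a calcium-binding protein gene, by 1.17 ± 1.29 with 19 of 22 higher. The class II gene H2-Eb1 and the lysozyme gene Lyz2, which is abundant in myeloid cells, had means of 1.14 ± 1.17 and 1.20 ± 1.59. Globin transcripts, markers of erythroid cells, were also among the highest, with a mean of 1.49 ± 1.55 for Hba-a1, 1.37 ± 1.72 for Hba-a2, 1.33 ± 1.39 for Hbb-bt and 1.24 ± 1.45 for Hbb-bs, each higher in 18 cell types, and the Hba-a1 and Hba-a2 copies are nearly identical, so their separate counts are uncertain. Camk2n1 had a mean of 0.86 ± 1.12 and the transcription factor gene Bhlhe40 0.92 ± 1.62.

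Among the lower genes were the DNA demethylases Tet1 (chr 10, 62804570 to 62908996, mean log2 fold change -0.42 ± 0.34, lower in 19 of 23 cell types) and Tet3 (-0.34 ± 0.47, 19 of 23) and the DNA methyltransferase Dnmt3a (-0.34 ± 0.36, 20 of 23). N4bp2l1 had the lowest mean, -0.84 ± 0.76, and the chemokine gene Ccl25 followed at -0.54 ± 0.59. Smc4, a condensin subunit, and Sesn1, a stress-induced sestrin, had means of -0.41 ± 0.48 and -0.40 ± 0.44. Sh3pxd2a (-0.45 ± 0.55), Fam102b (-0.35 ± 0.43), Dgkd (-0.35 ± 0.31), Jmy (-0.34 ± 0.40) and Tbcel (-0.33 ± 0.40) completed the named genes. In a model with cell type and 1 age term, 1431 genes were higher and 602 lower among 23420 tested, with adjusted p = 1.71e-33 for Ide and 0.000689 for Sh3pxd2a, the highest among the named genes. That model takes the libraries as replicates of a single change. A limma test on 1 fold change per cell type, over 5214 genes measured in every cell type, called 76 genes, and on means per tissue 22. Of the 10 named genes it held 8 were called over cell types, all but Bhlhe40 and Tet3 (adjusted p = 0.108 and 0.0524), and 3 over tissues, Ide, Tet1 and Dgkd. With genes missing in some cell types, chosen after the results were seen, 21 of the 24 named genes were called over cell types, all but Lyz2, Bhlhe40 and Tet3, and 6 over tissues, Ide, H2-Q7, H2-Eb1, Hba-a1, Hbb-bt and N4bp2l1.

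**Figure D2:**
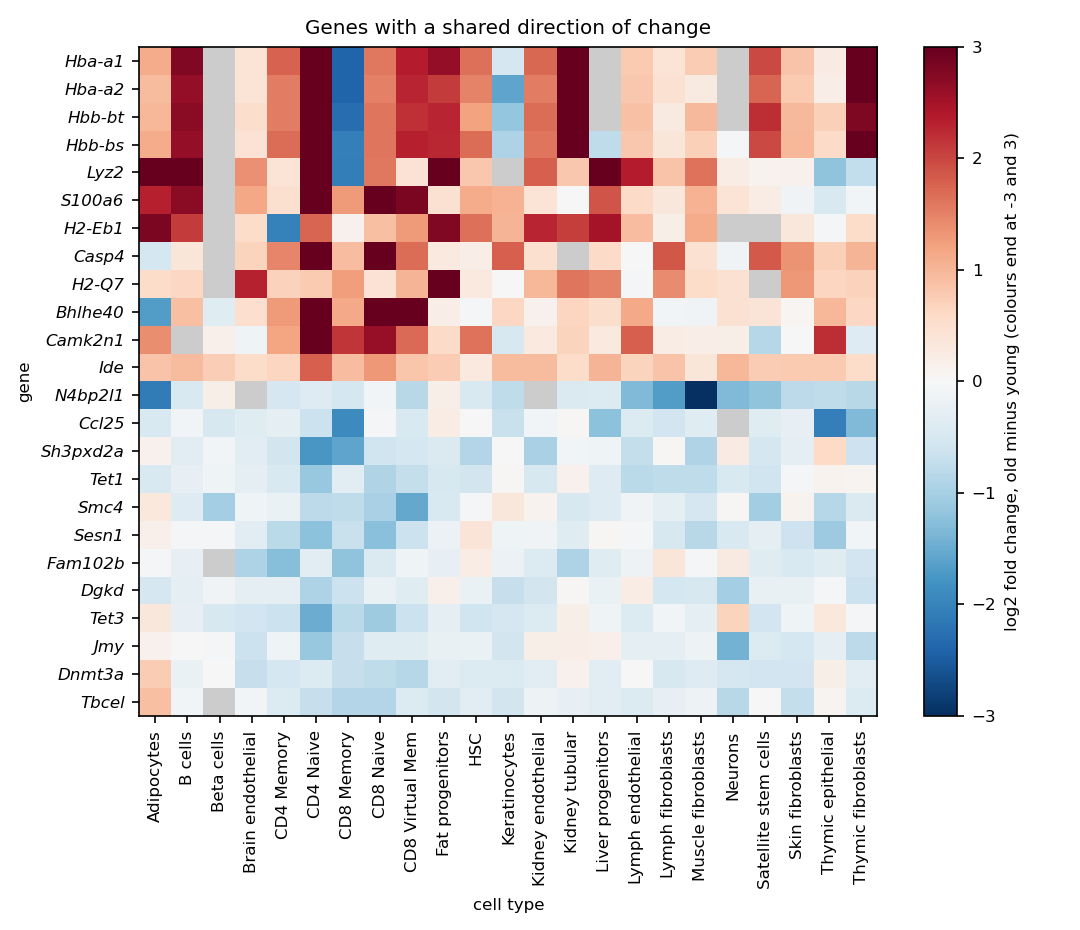
Heatmap of the log2 fold change, old minus young, of the genes named as shared (vertical axis) in each cell type (horizontal axis), red where higher and blue where lower in old animals, with colours ending at -3 and 3 and grey where a gene was not measured. Ide is red in 23 of 23 cell types.

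Counted over the separate tests, 1129 genes were higher in at least 2 cell types and 498 lower, and 827 genes passed in opposite directions in different cell types. Among genes that the naming rule allows, H2-Q7 and Ide were each higher in 10 cell types, which for H2-Q7 included brain and kidney endothelial cells, fat progenitors and thymic epithelial cells beside B cells and T cells. Jchain, the joining chain gene of immunoglobulins, was higher in 9 of the 13 cell types that measured it. The class II gene H2-Ab1, S100a6, Casp4 and Hba-a1 were each higher in 8, and Lilr4b, the iron-binding Lcn2 and the protease inhibitor Slpi in 7. H2-Ab1 and S100a6 were each lower in 1 other cell type. In the lower direction Dapl1 passed in 6 cell types, 5 of them T cell subsets, and was higher in 1. Pin4, the transcription factor gene Lef1, Cpm and Smc4 fell in 5 cell types each. Tcf7, Tmem108, Itm2a, the basement membrane collagen gene Col4a2 and Rapgef4 fell in 4, and Itm2a was higher in 1.

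Of 18 gene lists tested across cell types by a two-sided sign-flip permutation test, 8 were higher in old animals and 0 lower. The MHC class I presentation list was higher in 22 of 23 cell types, with a mean log2 fold change of 0.40 ± 0.25 (SD, permutation adjusted p = 0.000180, the smallest these permutations can give). In the model with cell type and age 15 of its 16 genes rose, and 15 adjusted over the list alone, among them the proteasome subunit gene Psmb8 (0.60 ± 0.37), H2-K1 (0.50 ± 0.35) and B2m (0.44 ± 0.26). Secreted inflammatory factors had a mean of 0.69 ± 0.85 (17 of 22, permutation adjusted p = 0.00216) and MHC class II presentation 0.86 ± 1.06 (17 of 20, 0.00745). Beside class II genes, B cell markers outside B cells had 0.443 (16 of 22, permutation adjusted p = 0.0591), the plasma cell genes Jchain, Mzb1 and Derl3 0.957 (18 of 22, 0.00408), and Lyz2 was higher in 18 of 21 cell types. Interferon-stimulated genes had 0.24 ± 0.32 (18 of 23, permutation adjusted p = 0.00745) and circadian clock genes 0.21 ± 0.31 (18 of 23, 0.00552). In that model 16 of 27 inflammatory factors rose, and 20 adjusted over the list alone, against 7 and 8 of 10 class II, 13 and 15 of 36 interferon-stimulated and 5 and 5 of 16 clock genes.

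AP-1 subunits (0.29 ± 0.46, 17 of 23, permutation adjusted p = 0.0166), T cell activation and exhaustion genes (0.68 ± 1.16, 14 of 19, 0.0190) and senescence-associated inhibitors (0.21 ± 0.35, 14 of 22, 0.0251) were also higher. Of 12 AP-1 genes 6 rose in the model with cell type and age, and 7 adjusted over the list alone, among them Batf (0.80 ± 0.68) and Fosb (0.53 ± 0.91). Of 7 inhibitors 4 rose, and 4 adjusted over the list alone, among them Cdkn2c (0.65 ± 0.81) and Cdkn1a (0.41 ± 0.90), and of 20 T cell activation genes 14 and 17. On means per tissue these 3 lists lost the call (permutation adjusted p = 0.246 for AP-1 subunits, 0.281 for T cell activation, 0.246 for the inhibitors). The inhibitors also lost it with the median of members (0.175) and without CD4 naive cells (0.0507).

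Immediate-early and heat-shock genes, which also respond to tissue dissociation, did not pass (0.21 ± 0.44, permutation adjusted p = 0.0636). They were called without adipocytes (0.0363), beta cells (0.0205), kidney endothelial cells (0.0484) or liver progenitors (0.0480). Unfolded protein response genes across cell types (0.13 ± 0.29, 0.0636) were called with the median of members (0.0205) and without adipocytes (0.0493) or satellite cells (0.00714). Complement components (0.36 ± 0.80, 0.0772) were called on means per tissue (0.0198) and without CD4 memory (0.0170) or CD8 memory cells (0.0131), extracellular matrix genes (-0.16 ± 0.45, 0.134) without adipocytes (0.0366), and imprinted growth genes (-0.15 ± 0.37, 0.122) without CD8 memory cells (0.0433). Cholesterol synthesis (-0.08 ± 0.25, 0.157), aged stem cell (0.13 ± 0.50, 0.309), nuclear oxidative phosphorylation (0.05 ± 0.22, 0.309), ribosomal protein (0.04 ± 0.28, 0.5263) and proliferation genes (0.04 ± 0.46, 0.648) were not called. Tested with fry within each cell type, 71 of 402 gene list tests passed, 57 higher and 14 lower. With camera and an estimated correlation 6 passed. Without each library in turn 38 of the 95 gene and marker list calls stayed past the threshold. In pairs of list counts the second is adjusted over the list alone, and genes given by "namely" belong to the first. In pairs of adjusted p the second is with an estimated correlation.

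**Figure D3:**
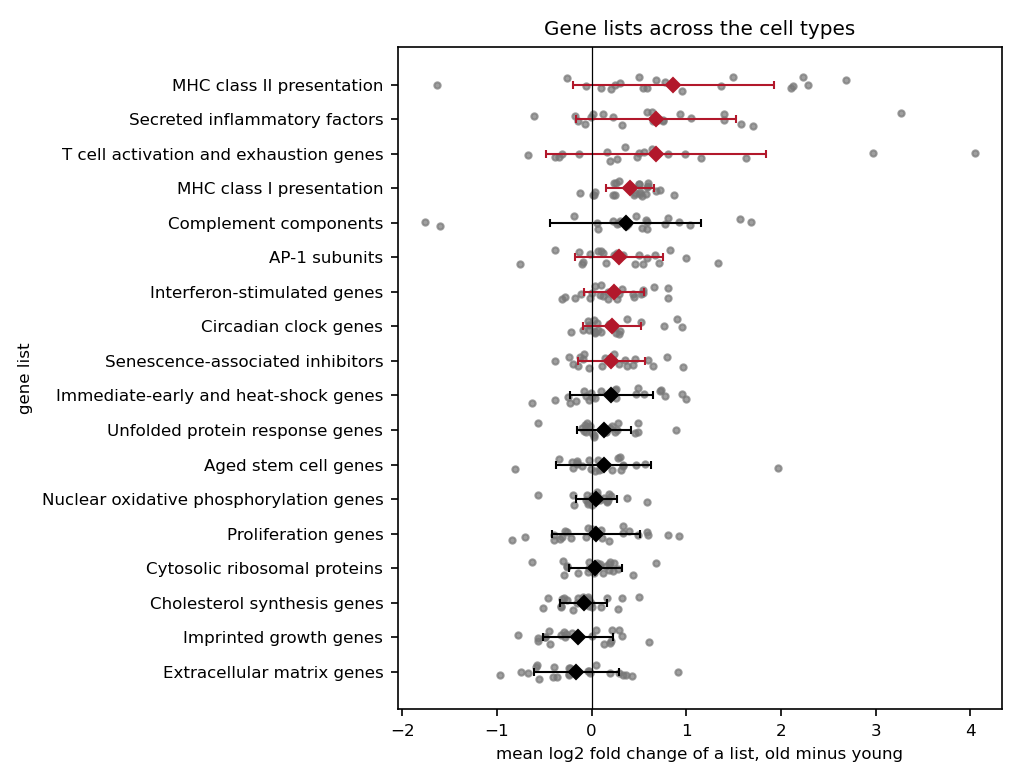
Mean log2 fold change, old minus young, of the members of each gene list, with 1 grey point per cell type, a diamond at the mean and a bar of 1 SD to each side, red where the permutation adjusted p is under 0.05. The MHC class I list lies above 0 in 22 of 23 cell types.

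In CD4 naive T cells from spleen (n = 4 young, 3 old), T cell activation and exhaustion genes rose with age, in 18 of 19, and 18 adjusted over the list alone (adjusted p = 0.000311, and 0.0327 with an estimated correlation), including Cxcr3 (6.83 to 122 CPM) and the inhibitory receptor gene Pdcd1 (14.1 to 231 CPM). Sostdc1 (chr 12, 36314139 to 36318452) went from 3.28 ± 0.747 to 313 ± 235 CPM (log2 6.52 ± 0.65, adjusted p = 0.000168). The cytokine gene Il21 (log2 5.65 ± 1.01), the transcription factor gene Tox2 (5.40 ± 0.52), Angptl2 (5.69 ± 0.63) and Gpm6b (5.15 ± 0.61) also rose. Secreted inflammatory factors rose in 5 and 6 of 8 (adjusted p = 0.00915 and 0.140), with Ccl5 from 659 to 7460.0 CPM, and MHC class I genes in 4 and 6 of 16 (adjusted p = 0.0144 and 0.205). Arhgap29 (chr 3, 121952541 to 122016753) fell from 29.5 ± 7.28 to 1.26 ± 0.712 CPM (log2 -4.27 ± 0.43, adjusted p = 0.000169). Satb1 (log2 -2.39 ± 0.42), Dapl1 (-2.90 ± 0.51), Adh1 (-2.47 ± 0.55) and Tdrp (-2.37 ± 0.30) fell too.

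Markers of other cell types moved in the same CD4 naive libraries. All 12 measured plasma cell markers rose (mean log2 4.31), as did 7 of 7 neutrophil (4.20), 6 of 7 erythroid (3.14) and 3 of 5 macrophage markers, and 3 of 5 thymocyte markers fell. None of these 5 marker lists passed its own test. Without old replicate 3, with 14.8% immunoglobulin counts, 7 of 11 plasma cell (mean log2 1.78), 7 of 7 neutrophil (2.21), 6 of 7 erythroid (2.77) and 0 of 5 macrophage markers rose and 2 of 5 thymocyte markers fell, a test chosen after the results were seen. Of all genes 833 were higher and 302 lower, and the count was 692 and 712 without young replicates 2 and 4, and 1909 without old replicate 1. Adh1 lost the call without some library (adjusted p up to 0.0649) and was at -3.73 without old replicate 1, and Il21 was at 4.11 without old replicate 3.

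CD4 memory T cells (n = 5 young, 5 old) had 152 higher and 173 lower genes. Eomes, a transcription factor gene of effector T cells, rose from 17.98 ± 6.84 to 181 ± 169 CPM (log2 3.32 ± 0.59, adjusted p = 0.0102). Ecel1 (chr 1, 87147655 to 87156521, log2 3.91 ± 0.50), Arnt2 (3.57 ± 0.44), Ier3 (3.42 ± 0.71) and Cdk5r1 (3.21 ± 0.44) rose. T cell activation genes rose in 8 of 20, and 11 adjusted over the list alone (adjusted p = 0.0417, and 0.271 with an estimated correlation), with the granzyme gene Gzmk from 27.8 to 246 CPM. Siglech, a gene of plasmacytoid dendritic cells, fell from 274 ± 191 to 32.3 ± 31.1 CPM (log2 -2.98 ± 0.58, adjusted p = 0.0149). Cd209d (log2 -3.08 ± 0.52), Clec10a (-2.76 ± 0.65), Stra6l (chr 4, 45848664 to 45887008, -3.13 ± 0.47) and Adap2 (-2.86 ± 0.54) fell as well. Dendritic cell markers fell in 5 and 5 of 7 (adjusted p = 0.00651 and 0.180), and beside them MHC class II genes in 8 and 10 of 10 (adjusted p = 0.0364 and 0.222), with Cd74 from 1586 to 578 CPM.

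Proliferation genes fell in CD4 memory cells in 4 of 33, and 17 adjusted over the list alone (adjusted p = 0.0496, and 0.271 with an estimated correlation), with Mki67 from 85.3 to 37.3 CPM, cholesterol synthesis genes in 2 and 6 of 19 (adjusted p = 0.00245 and 0.0849) and interferon-stimulated genes in 2 and 6 of 32 (adjusted p = 0.0339 and 0.241). MHC class I genes rose in 1 and 2 of 16 (adjusted p = 0.00943 and 0.159), T cell markers in 1 and 5 of 9 (adjusted p = 0.0385 and 0.310), and 3 of 6 erythroid markers rose. Calls numbered 168 and 133 without young replicates 1 and 2, and 213 without old replicate 5, and Ier3 and Clec10a lost the call without some library (adjusted p up to 0.0990).

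The age change of CD4 memory minus that of CD4 naive cells was tested as an interaction. Lef1, a transcription factor gene of naive T cells, went from 1424 ± 114 to 289.8 ± 208 CPM in naive cells and from 256 ± 40.6 to 226 ± 144 CPM in memory cells (log2 2.11 ± 0.53, adjusted p = 0.0257). Ly6c1 (2.43 ± 0.63), Als2cl (2.18 ± 0.55), Smad7 (2.02 ± 0.58) and Arhgap29 (2.91 ± 0.83) differed likewise. Batf3, a transcription factor gene of dendritic cells, went from 0.697 ± 0.162 to 9.39 ± 8.25 CPM in naive and from 27.1 ± 5.63 to 4.41 ± 4.63 CPM in memory cells (-5.93 ± 1.06, adjusted p = 0.00295). Sirpa (-6.22 ± 1.31), Skint3 (-6.47 ± 1.49), Rnd3 (-6.09 ± 1.09) and Stra6l (-5.74 ± 1.21) moved in that direction. Without naive old replicate 3 these 4 were at -3.15, -2.50, -3.92 and -4.34, and all but Rnd3 lost the call. Without naive young replicate 1 Stra6l was at -9.33. Of the 10 named genes all but Batf3 and Rnd3 lost the call without some library (adjusted p up to 0.361). Of 13562 genes 58 were higher and 570 lower. The count was 416 without naive young replicate 4, and 1176 and 258 without naive old replicates 1 and 3. Both subsets shared 111 risen genes, where independent lists would share 10.9, and 10 fallen genes against 3.42.

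CD8 naive T cells (n = 4 young, 3 old) had 595 higher and 327 lower genes. The chemokine gene Ccl5 rose from 476 ± 25.5 to 38418 ± 6559 CPM (log2 6.33 ± 0.17, adjusted p = 4.25e-12). Penk (log2 6.91 ± 0.38), Kcnip3 (chr 2, 127456498 to 127522094, 7.40 ± 0.59), Lmo1 (6.39 ± 0.53) and Klrg1 (6.22 ± 0.63) rose. T cell activation genes rose in 16 of 17, and 16 adjusted over the list alone (adjusted p = 4.37e-05, and 0.0327 with an estimated correlation), including Gzmk (11.03 to 578 CPM) and Pdcd1 (3.53 to 139.5 CPM). Pced1b fell from 488 ± 182 to 117 ± 43.8 CPM (log2 -2.07 ± 0.31, adjusted p = 0.000302). St8sia1 (chr 6, 142821545 to 142964452, log2 -2.25 ± 0.32), Slc6a19 (-2.09 ± 0.27), Kcna2 (-2.04 ± 0.51) and Tdrp (-2.03 ± 0.21) fell.

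Secreted inflammatory factors rose in CD8 naive cells in 4 of 14, and 4 adjusted over the list alone (adjusted p = 4.37e-05, and 0.112 with an estimated correlation), MHC class I genes in 5 and 12 of 16 (adjusted p = 0.00191 and 0.0919), proliferation genes in 5 and 9 of 30 (adjusted p = 0.0114 and 0.205), with Top2a from 29.3 to 67.0 CPM, and unfolded protein response genes in 6 and 7 of 17 (adjusted p = 0.0251 and 0.234), with the chaperone gene Hspa5 from 309.9 to 636 CPM. Thymocyte markers fell in 2 and 2 of 5 (adjusted p = 0.0430 and 0.310), with Tcf7 from 829 to 442 CPM. Dendritic cell markers fell in 1 and 1 of 3 (adjusted p = 0.0373 and 0.577), namely Ccr9, while Xcr1 rose. All 5 measured neutrophil markers (mean log2 3.26), 4 of 5 erythroid (1.63) and 3 of 8 plasma cell markers (1.45) rose, and these 3 lists did not pass. The adipocyte gene Adipoq, named after its values were seen, had 252 ± 26.1 CPM in young and 232 ± 5.18 CPM in old libraries, and at most 3.10 CPM in any other T cell library. Calls numbered 593 without old replicate 1, and Kcna2 lost the call without some library (adjusted p up to 0.106) and was at -3.32 without old replicate 2.

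CD8 memory T cells (n = 3 young, 3 old) had 49 higher and 68 lower genes. Gzmk rose from 30.9 ± 9.47 to 388 ± 203 CPM (log2 3.66 ± 0.41, adjusted p = 0.00628). Epha3 (chr 16, 63543534 to 63864175, log2 6.21 ± 0.69), Penk (3.31 ± 0.65), H2-Q10 (4.44 ± 0.53) and Tmprss13 (3.34 ± 0.51) rose. Ncr1, a natural killer cell receptor gene, fell from 50.7 ± 18.5 to 3.78 ± 1.07 CPM (log2 -3.75 ± 0.42, adjusted p = 0.00628). Klra4 (chr 6, 130043731 to 130067271, log2 -5.27 ± 0.60) and Klra8 (-5.15 ± 0.69), near copies of uncertain count, Igf1 (-3.61 ± 0.39) and the complement gene C6 (-3.52 ± 0.67) fell. T cell activation genes rose in 6 of 19, and 9 adjusted over the list alone (adjusted p = 0.0435, and 0.245 with an estimated correlation), with Pdcd1 from 15.7 to 99.0 CPM, and MHC class I genes in 1 and 11 of 16 (adjusted p = 0.0379 and 0.271). Macrophage markers fell in 5 and 10 of 10 (adjusted p = 0.0373 and 0.252), microglia markers in 2 and 3 of 5 (adjusted p = 0.0431 and 0.310) and complement genes in 3 and 5 of 7 (adjusted p = 0.0338 and 0.205), with C1qa, on all 3 of these lists, from 70.0 to 7.83 CPM. Calls numbered 3, 4 and 45 without young replicates 2, 3 and 4, and 36, 878 and 25 without old replicates 1, 2 and 3, and each of the 10 named genes lost the call without some library (adjusted p up to 0.163).

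Virtual memory CD8 T cells (n = 5 young, 5 old), a memory-type subset that forms without antigen, had 278 higher and 119 lower genes. Fgl2 (chr 5, 21372642 to 21378374) rose from 6.24 ± 2.51 to 159.6 ± 35.0 CPM (log2 4.61 ± 0.26, adjusted p = 8.05e-08). S1pr5 (log2 4.42 ± 0.48), Gzmk (4.10 ± 0.64), Spats2 (4.02 ± 0.47) and Socs2 (3.96 ± 0.52) rose. The transcription factor gene Myb (chr 10, 21124935 to 21160984) fell from 79.9 ± 34.5 to 4.54 ± 2.34 CPM (log2 -4.13 ± 0.39, adjusted p = 1.35e-05). Id3 (log2 -3.73 ± 0.40), Atp1b1 (-3.75 ± 0.33), Slc28a2b (-3.42 ± 0.44) and Tmem108 (-2.78 ± 0.23) fell. T cell activation genes rose in 8 of 13, and 8 adjusted over the list alone (adjusted p = 0.000311, and 0.0492 with an estimated correlation), with Gzmb from 8.41 to 124 CPM, and MHC class I genes in 7 and 13 of 16 (adjusted p = 0.000150 and 0.0416), with H2-K1 from 1777 to 3155 CPM. Secreted inflammatory factors rose in 1 and 3 of 7 (adjusted p = 0.0473 and 0.306), namely Ccl5, and senescence-associated inhibitors in 1 and 1 of 4 (adjusted p = 0.0473 and 0.364), namely Cdkn1a. Thymocyte markers fell in 1 and 1 of 4 (adjusted p = 0.0410 and 0.416), namely Tcf7. Plasma cell markers rose in 3 of 8 (1 of 8 without old replicate 4).

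For CD8 memory minus CD8 naive cells, Gzma, a granzyme gene, went from 7.56 ± 4.01 to 130.1 ± 38.8 CPM in naive and from 806 ± 403 to 154 ± 79.5 CPM in memory cells (log2 -6.53 ± 0.65, adjusted p = 1.61e-05). The chemokine receptor gene Ccr2 (-6.37 ± 0.57) and Chst2 (-6.63 ± 0.69) moved likewise. Nt5e, which encodes CD73, went from 31.5 ± 9.88 to 15.4 ± 2.41 CPM in naive and from 13.4 ± 1.20 to 43.4 ± 8.14 CPM in memory cells (2.73 ± 0.42, adjusted p = 0.00118). Pced1b (3.65 ± 0.73) and Trim30c (8.24 ± 1.84) differed in that direction. Trim30c had 70.6 ± 115 CPM in young naive libraries and was at 5.75 without naive young replicate 1. Slc38a5 and Pdzk1ip1 had 0 counts in young naive libraries and Ehd2 in young memory libraries, so no fold is given for them. These 3 and Trim30c lost the call without some library (adjusted p up to 0.208). Of 12557 genes 91 were higher and 280 lower. The count was 237 without naive young replicate 1, 238 and 241 without naive old replicates 1 and 2, 227 without memory young replicate 3, and 986 and 225 without memory old replicates 2 and 3. Both subsets shared 36 risen genes, against 2.65 for independent lists, and 7 fallen genes against 1.13.

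In B cells from bone marrow (n = 5 young, 4 old), Car1, an erythroid carbonic anhydrase gene (chr 3, 14766216 to 14808368), rose from 0.993 ± 0.287 to 21.2 ± 5.52 CPM (log2 4.31 ± 0.35, adjusted p = 6.07e-07). Ctsg, a neutrophil protease gene (log2 4.25 ± 0.37), Lrg1 (3.90 ± 0.37), Tnfaip2 (4.11 ± 0.45) and Apol11b, which has near copies and an uncertain count (3.90 ± 0.35), rose. Neutrophil markers rose in 10 of 10, and 10 adjusted over the list alone (adjusted p = 0.000712, and 0.180 with an estimated correlation), with S100a8 from 245 to 2713 CPM, erythroid markers in 7 and 7 of 7 (adjusted p = 0.000747 and 0.180), plasma cell markers in 5 and 6 of 11 (adjusted p = 0.0185 and 0.222) and macrophage markers in 1 and 2 of 3 (adjusted p = 0.00256 and 0.222). Mdm1 (chr 10, 118141811 to 118168997) fell from 38.0 ± 3.30 to 18.4 ± 4.55 CPM (log2 -1.04 ± 0.19, adjusted p = 0.00336). Tatdn1 (log2 -1.03 ± 0.26), Arhgef39 (-1.02 ± 0.25), Rnf146 (-0.94 ± 0.19) and Igsf3 (-0.90 ± 0.23) fell. Of all genes 280 were higher and 93 lower.

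MHC class II genes rose in the same B cell libraries in 7 of 9, and 9 adjusted over the list alone (adjusted p = 7.25e-05, and 0.0492 with an estimated correlation), with Cd74 from 165 to 546 CPM, and MHC class I genes in 2 and 3 of 16 (adjusted p = 0.00157 and 0.112). AP-1 subunits rose in 2 and 6 of 8 (adjusted p = 0.00520 and 0.159), with Fos from 102 to 275 CPM, and immediate-early and heat-shock genes in 4 and 8 of 26 (adjusted p = 0.0257 and 0.271). Interferon-stimulated genes rose in 2 and 2 of 29 (adjusted p = 0.0251 and 0.222), secreted inflammatory factors in 2 and 2 of 4 (adjusted p = 0.0116 and 0.305), complement genes in 3 and 3 of 5 (adjusted p = 0.0473 and 0.275) and T cell activation genes in 2 and 2 of 7 (adjusted p = 0.0101 and 0.205). Proliferation genes fell in 9 and 22 of 35 (adjusted p = 0.0218 and 0.205), with Mki67 from 794 to 558 CPM. Tatdn1, Arhgef39 and Igsf3 lost the call without some library (adjusted p up to 0.146).

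HSC from bone marrow (n = 4 young, 7 old) had 668 higher and 531 lower genes. Mt2, a metallothionein gene (chr 8, 94172664 to 94173568), rose from 3.83 ± 2.38 to 76.1 ± 9.56 CPM (log2 4.27 ± 0.26, adjusted p = 7.35e-08). Zg16 (log2 4.24 ± 0.46), Matn4 (3.86 ± 0.38), the nuclear receptor gene Rorb (3.78 ± 0.21) and Chrm3 (3.74 ± 0.33) rose. Vegfa (chr 17, 46016993 to 46032369) fell from 20.6 ± 13.7 to 4.98 ± 1.01 CPM (log2 -2.09 ± 0.32, adjusted p = 0.000686). Mc5r (log2 -1.79 ± 0.25), Rnase6 (-1.61 ± 0.16), Arhgap30 (-1.48 ± 0.18) and Arhgap15 (-1.45 ± 0.13) fell. Aged stem cell genes rose in 13 of 13, and 13 adjusted over the list alone (adjusted p = 3.80e-09, and 0.000972 with an estimated correlation), with Nupr1 from 103 to 689 CPM and Clu from 41.7 to 257 CPM. MHC class II genes rose in 5 and 5 of 10 (adjusted p = 0.00464 and 0.231) and MHC class I genes in 6 and 10 of 16 (adjusted p = 0.00157 and 0.140). Ribosomal protein genes rose in 11 and 28 of 86 (adjusted p = 0.0196 and 0.275), with Rps4l lower, and senescence-associated inhibitors in 1 and 2 of 5 (adjusted p = 0.0261 and 0.271), namely Cdkn2c. Plasma cell markers rose in 4 of 9 (mean log2 3.47). Calls numbered 762 and 701 without young replicates 1 and 2, and 780 without old replicate 5.

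Thymic epithelial cells (n = 5 young, 5 old) had 860 higher and 671 lower genes. Otog (chr 7, 46240987 to 46311434) rose from 1.89 ± 1.15 to 102 ± 33.1 CPM (log2 5.46 ± 0.32, adjusted p = 2.79e-08). The growth factor gene Fgf7 (log2 4.13 ± 0.23), Ecel1 (4.38 ± 0.27), Dhrs9 (3.96 ± 0.26) and Ush1c (3.88 ± 0.37) rose. Ackr4, an atypical chemokine receptor gene, fell from 426 ± 69.3 to 67.4 ± 13.1 CPM (log2 -2.66 ± 0.16, adjusted p = 2.79e-08). Zfp385b (chr 2, 77410634 to 77819639, log2 -3.90 ± 0.56), Dlgap1 (-2.84 ± 0.66), Vsig8 (-2.69 ± 0.27) and Tmeff2 (-2.64 ± 0.34) fell. Fibroblast markers rose in 7 of 8, and 7 adjusted over the list alone (adjusted p = 0.00639, and 0.310 with an estimated correlation), and beside them extracellular matrix genes in 11 and 12 of 25 (adjusted p = 0.00134 and 0.159), with Postn from 113 to 268 CPM, and complement genes in 6 and 7 of 13 (adjusted p = 0.00421 and 0.170), with C4b from 16.4 to 75.0 CPM. T cell markers fell in 5 and 6 of 6 (adjusted p = 0.00188 and 0.222) and thymocyte markers in 4 and 4 of 6 (adjusted p = 0.0431 and 0.389), with Rag1 from 13.2 to 3.39 CPM.

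Secreted inflammatory factors rose in thymic epithelial cells in 5 of 19, and 8 adjusted over the list alone (adjusted p = 0.0257, and 0.278 with an estimated correlation), with Ccl11 from 379 to 1518 CPM, while Cxcl12 fell from 578 to 252 CPM, and AP-1 subunits rose in 5 and 6 of 9 (adjusted p = 0.0496 and 0.343). MHC class II genes fell in 3 and 3 of 10 (adjusted p = 0.0251 and 0.315), namely H2-DMa, H2-DMb1 and H2-DMb2, and cholesterol synthesis genes in 3 and 5 of 21 (adjusted p = 0.0339 and 0.271). Keratinocyte markers rose in 2 and 2 of 4 (adjusted p = 0.0385 and 0.672), with Krt5 from 609 to 1134 CPM, and Trp63 fell. Mesothelial markers rose in 1 and 1 of 3 (adjusted p = 0.0431 and 0.468), oligodendrocyte markers in 1 and 2 of 3 (adjusted p = 0.0373 and 0.540), and plasma cell markers in 6 of 10.

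In thymic fibroblasts (n = 4 young, 4 old), 169 genes were higher and 66 lower. The globin genes Hba-a2 (chr 11, 32296489 to 32297298, log2 4.72 ± 0.61), Hba-a1 (3.71 ± 0.50) and Hbb-bs (3.64 ± 0.50) rose, with 4 of 4 erythroid markers. Grem1, a BMP antagonist gene, rose from 2.61 ± 1.58 to 22.2 ± 7.41 CPM (log2 3.10 ± 0.44, adjusted p = 0.00145). Jchain (log2 2.32 ± 0.30) rose beside plasma cell markers in 5 of 9, and 7 adjusted over the list alone (adjusted p = 0.0439, and 0.222 with an estimated correlation). The receptor kinase gene Ret fell from 32.8 to 7.74 CPM (log2 -2.07 ± 0.25), and the imprinted noncoding RNA H19 (chr 7, 142575529 to 142578143, log2 -2.14 ± 0.38), Rac2 (-1.77 ± 0.38), Edn1 (-1.69 ± 0.29) and Itm2a (-1.56 ± 0.22) fell. Extracellular matrix genes fell in 13 and 18 of 25 (adjusted p = 0.00424 and 0.0604), with Sparc from 2977 to 1217 CPM, and T cell markers in 2 and 6 of 6 (adjusted p = 0.0386 and 0.252). Secreted inflammatory factors rose in 6 and 12 of 21 (adjusted p = 0.0218 and 0.140), with Il6 from 47.8 to 169.7 CPM, while Mmp9 fell. Interferon-stimulated genes rose in 5 and 10 of 33 (adjusted p = 0.0251 and 0.173), MHC class I genes in 2 and 9 of 16 (adjusted p = 0.0261 and 0.205), AP-1 subunits in 4 and 7 of 10 (adjusted p = 0.0449 and 0.190) and complement genes in 1 and 5 of 12 (adjusted p = 0.00225 and 0.159). Calls numbered 149 without young replicate 2, and 141, 136 and 148 without old replicates 1, 2 and 3, and Rac2 lost the call without some library (adjusted p up to 0.0764).

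Adipocytes from visceral fat (n = 3 young, 5 old) had 811 higher and 586 lower genes. Trem2, a receptor gene of macrophages, rose from 4.86 ± 1.34 to 130.0 ± 76.1 CPM (log2 4.73 ± 0.52, adjusted p = 0.000383). Rnf128 (chr X, 139563316 to 139673145, log2 5.62 ± 0.54), Atp6v0d2 (4.97 ± 0.67), Slc5a7 (5.26 ± 0.77) and Trdn (5.17 ± 0.51) rose. Pon1 fell from 38.1 ± 17.3 to 1.91 ± 0.929 CPM (log2 -4.30 ± 0.40, adjusted p = 0.000135). Rgs16 (log2 -3.70 ± 0.31) fell. The urinary protein genes Mup9 (chr 4, 60418046 to 60421952, log2 -6.54 ± 0.92), Mup3 (-3.93 ± 0.46) and Mup11 (-3.90 ± 0.47), near copies of uncertain count, fell, and Mup9 was at -4.62 without young replicate 3. Extracellular matrix genes rose in 8 of 25, and 11 adjusted over the list alone (adjusted p = 0.0360, and 0.271 with an estimated correlation). Beside them 8 of 10 macrophage (mean log2 3.01), 4 of 8 fibroblast (1.52), 5 of 7 plasma cell and 3 of 5 mesothelial markers rose. Of class II genes 6 of 7 rose (adjusted p = 0.0529), and 25 of 76 oxidative phosphorylation genes fell (0.0572). Calls numbered 689, 457 and 823 without young replicates 1, 2 and 3.

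In progenitors from the same fat (n = 4 young, 3 old), 44 genes were higher and 25 lower. Bmp3, a growth factor gene, rose from 1.19 ± 0.952 to 31.3 ± 16.6 CPM (log2 4.54 ± 0.50, adjusted p = 0.00135). Jchain (chr 5, 88519809 to 88527891, log2 5.19 ± 0.79), Ankrd1 (4.25 ± 0.55), H2-Q7 (3.23 ± 0.46) and Dmkn (2.73 ± 0.37) rose. Pdgfrl (chr 8, 40926212 to 40990785) fell from 30.3 ± 3.44 to 3.95 ± 0.944 CPM (log2 -2.92 ± 0.27, adjusted p = 0.000387). Itm2a (log2 -2.26 ± 0.22), Spon1 (-2.05 ± 0.32) and Wfdc1 (-1.99 ± 0.26) fell. Extracellular matrix genes fell in 1 of 25, and 12 adjusted over the list alone (adjusted p = 0.00925, and 0.112 with an estimated correlation), namely the elastin gene Eln, and fibroblast markers in 0 and 1 of 8 (adjusted p = 0.0431 and 0.252). The 3 measured plasma cell markers rose. Calls numbered 32, 38 and 24 without young replicates 1, 2 and 4, and 33 and 227 without old replicates 1 and 3. Jchain, H2-Q7 and Spon1 lost the call without some library (adjusted p up to 0.0831), and Jchain was at 3.72 without old replicate 2.

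Endothelial cells of the kidney (n = 4 young, 3 old) had 113 higher and 63 lower genes. Sost, an inhibitor of Wnt signalling (chr 11, 101962458 to 101967015), rose from 38.2 ± 21.3 to 511 ± 228 CPM (log2 3.82 ± 0.40, adjusted p = 3.32e-05). The class II genes Cd74 (log2 2.99 ± 0.24), H2-DMb1 (2.71 ± 0.33) and H2-Eb1 (2.28 ± 0.25) and Lrg1 (2.66 ± 0.28) rose. The urea transporter gene Slc14a1 fell from 157 ± 15.1 to 30.1 ± 4.42 CPM (log2 -2.37 ± 0.19, adjusted p = 1.00e-06). Agtr1a, an angiotensin receptor gene (chr 13, 30336441 to 30382867, log2 -2.53 ± 0.58), and Itga8 (-2.03 ± 0.33) fell. The smooth muscle genes Myh11 (log2 -2.40 ± 0.57) and Myl9 (-2.10 ± 0.50) fell, calls that DESeq2 did not make, beside 3 of 7 mural cell markers. MHC class II genes rose in 6 of 7, and 7 adjusted over the list alone (adjusted p = 0.00925, and 0.140 with an estimated correlation) and MHC class I genes in 4 and 8 of 16 (adjusted p = 0.0249 and 0.175). All 4 measured erythroid markers rose (mean log2 1.63). Calls numbered 378, 114 and 88 without young replicates 1, 2 and 4, and 81, 55 and 67 without old replicates 1, 2 and 3. Agtr1a, Myh11 and Myl9 lost the call without some library (adjusted p up to 0.165), and without young replicate 3 Myh11 was at -1.54 and Myl9 at -1.13.

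Kidney tubular cells (n = 3 young, 4 old) had 494 higher and 545 lower genes. Sult2a3 (chr 7, 14067446 to 14123044) rose from 6.32 ± 2.44 to 101 ± 40.5 CPM (log2 4.03 ± 0.37, adjusted p = 0.000302). The BMP antagonist gene Grem1 (log2 3.30 ± 0.45) and the globin genes Hba-a2 (3.99 ± 0.74), Hba-a1 (3.63 ± 0.65) and Hbb-bt (3.35 ± 0.53) rose. So did 4 of 5 erythroid, 4 of 4 plasma cell and 4 of 8 macrophage markers. Kap, the androgen-regulated kidney protein gene (chr 6, 133849851 to 133853762), fell from 527 ± 204 to 71.0 ± 97.9 CPM (log2 -2.90 ± 0.70, adjusted p = 0.0267), a call that DESeq2 did not make and that was lost without some library (adjusted p up to 0.0861, without young replicate 1, which had 62.2 CPM of Y-linked counts), with log2 -4.56 without old replicate 2. The complement gene C3 (log2 -2.61 ± 0.36), Sptssb (-2.42 ± 0.37), Lypd2 (-2.30 ± 0.27) and Cpn1 (-2.18 ± 0.37) fell, and so did 4 of 6 proximal tubule markers (mean log2 -1.38). MHC class II genes rose in 6 of 7, and 7 adjusted over the list alone (adjusted p = 0.0473, and 0.275 with an estimated correlation), with H2-Aa from 15.4 to 131 CPM, and T cell activation genes in 1 and 1 of 3 (adjusted p = 0.0267 and 0.355), namely Tox. Astrocyte markers fell in 2 and 2 of 5 (adjusted p = 0.0336 and 0.310), namely Aqp4 and Slc1a2. Calls numbered 349 and 607 without young replicates 1 and 2, and 638 and 553 without old replicates 1 and 4.

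Cells labelled liver progenitors (n = 3 young, 3 old) had 72 higher and 23 lower genes. The neutrophil gene S100a9 (chr 3, 90692632 to 90695721) rose from 0.801 ± 0.841 to 197 ± 243 CPM (log2 7.67 ± 1.06, adjusted p = 0.000670). Elane (log2 6.46 ± 0.91), Mpo (6.15 ± 0.89), Camp (6.02 ± 0.74) and Ngp (5.95 ± 0.83) rose beside all 7 measured neutrophil markers (mean log2 5.62). Without old replicate 3 these 5 genes stayed called, at 5.91, 5.45, 4.91, 4.95 and 4.32. The imprinted gene Peg3 fell from 440.2 ± 93.4 to 123 ± 21.3 CPM (log2 -1.84 ± 0.19, adjusted p = 4.04e-05). Dcx (log2 -2.42 ± 0.38), Snorc (chr 1, 87470271 to 87475482, -2.99 ± 0.43) and Bex1 (-2.02 ± 0.23) fell. Ak1 fell (log2 -1.75 ± 0.39), a call that DESeq2 did not make. MHC class II genes rose in 5 of 6, and 6 adjusted over the list alone (adjusted p = 0.0327, and 0.173 with an estimated correlation), cholesterol synthesis genes in 2 and 7 of 24 (adjusted p = 0.0267 and 0.173), and complement genes in 1 and 3 of 6 (adjusted p = 0.0450 and 0.271), namely C4b. Some hepatocyte genes, named after their values were seen, rose, namely Serpina1c from 240 ± 53.5 to 710 ± 176, Fgg from 107 ± 28.1 to 334 ± 63.4 and Hp from 15.8 ± 5.33 to 87.2 ± 38.2 CPM, though the hepatocyte list had 0 of 5 called (fry adjusted p = 0.540). Of their own markers Epcam (mean 745 CPM), Krt19 (259), Sox9 (2096) and Spp1 (20951) had a higher mean than in any other sorted type. Insulin transcripts were present at both ages, Ins2 at 38203 ± 2292 and 38394 ± 3175 CPM, against 522412 ± 76144 and 484138 ± 86287 CPM in beta cells, and the libraries scored most often highest on the beta cell list. Calls numbered 56 without young replicate 1, and 50 without old replicate 3, and Ak1 lost the call without some library (adjusted p up to 0.168).

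Beta cells of the pancreas (n = 4 young, 4 old) had 75 higher and 108 lower genes. Fmo1 rose from 42.1 ± 14.0 to 322 ± 105 CPM (log2 2.94 ± 0.27, adjusted p = 0.000101). B3galt1 (chr 2, 67565871 to 68122689, log2 3.77 ± 0.34), the tight junction gene Cldn8 (2.64 ± 0.30), Neb (2.47 ± 0.25) and Matn2 (2.45 ± 0.28) rose. The neuropeptide gene Gal fell from 244 ± 216 to 6.01 ± 2.71 CPM (log2 -5.61 ± 0.63, adjusted p = 0.000260). The hepcidin gene Hamp2 (log2 -5.74 ± 0.64), Tmed11 (-6.91 ± 0.77), Cabp2 (-5.78 ± 0.72) and the amylase gene Amy2a5 (chr 3, 113247178 to 113258837, -9.94 ± 1.40), with near copies and an uncertain count, fell. Acinar markers fell in 7 of 7, and 7 adjusted over the list alone (adjusted p = 0.0336, and 0.222 with an estimated correlation), with Cela1 from 18363 to 728 CPM. Young replicate 3 stood apart, with 2692 CPM of Amy2a5 and 180.2 in the nearest other. Without it the log2 of Amy2a5 in Beta cells was -7.53, and acinar markers had adjusted p = 0.0431. They lost the call without old replicate 1, 2 or 4 (adjusted p = 0.0520, 0.0518 and 0.0504). Immediate-early and heat-shock genes fell in 3 and 14 of 22 (adjusted p = 0.0218 and 0.159), AP-1 subunits in 1 and 4 of 7 (adjusted p = 0.0251 and 0.159), namely Atf3, and extracellular matrix genes in 1 and 1 of 6 (adjusted p = 0.0146 and 0.355), namely Serpinh1.

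Brain endothelial cells (n = 3 young, 4 old) had 51 higher and 36 lower genes. Cyp1b1 (chr 17, 79701537 to 79715061) rose from 1.69 ± 0.907 to 27.3 ± 3.48 CPM (log2 4.01 ± 0.36, adjusted p = 0.00116). The antiviral gene Oas2 (log2 2.61 ± 0.37) and Rasgrf2 (2.37 ± 0.26) rose. H2-Q7 (log2 2.30 ± 0.31) and H2-Q6 (2.30 ± 0.29), near copies of uncertain count, rose. The stress gene Gadd45a (chr 6, 67035096 to 67037457) fell from 152 ± 42.6 to 45.3 ± 16.7 CPM (log2 -1.73 ± 0.26, adjusted p = 0.0135). Nrep (log2 -1.65 ± 0.18) and Auts2 (-1.48 ± 0.25) fell. For Arf5 in Brain endothelial cells the fall of log2 -1.40 ± 0.27 lost the call with RLE size factors (adjusted p = 0.0506). Aged stem cell genes rose in 1 of 10, and 3 adjusted over the list alone (adjusted p = 0.0218, and 0.159 with an estimated correlation), namely the clotting gene Vwf, and endothelial markers fell in 0 and 1 of 8 (adjusted p = 0.0431 and 0.389). Replicate numbers paired these libraries, and with the replicate block 82 genes were higher and 130 lower, 212 in all, while these 2 lists lost the call (adjusted p = 0.0992 and 0.105). Calls numbered 22 and 33 without young replicates 3 and 4, and 137, 39 and 36 without old replicates 1, 3 and 4. Oas2, Gadd45a, Auts2 and Arf5 lost the call without some library (adjusted p up to 0.227).

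Neurons of the cerebrum (n = 2 young, 3 old) had 1 higher and 3 lower genes, all outside the naming rule and chosen after their values were seen, against 378 genes with DESeq2 and 1192 with no filter. The noncoding RNA model Gm26917 rose from 3854 ± 642 to 33657 ± 14911 CPM (log2 3.13 ± 0.38, adjusted p = 0.0258). The small nuclear RNA models Gm23934 (log2 -5.59 ± 0.55), Gm24205 (-6.96 ± 0.39) and Gm22360 (-8.31 ± 0.33) fell. On balance 5 lists were higher with 0 members called, also adjusted over the list alone. They were secreted inflammatory factors (adjusted p = 0.0386), MHC class I (0.0455), oxidative phosphorylation (0.0433), complement (0.0257) and aged stem cell genes (0.0114), and with an estimated correlation adjusted p was 0.295 to 0.456. Total counts were 566292 to 960128 in old and 2183970 to 2680065 in young libraries. Calls numbered 86 and 679 without young replicates 3 and 4, and 2 without old replicate 2, where a lone young library was assumed to vary like the others.

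Keratinocytes of the skin (n = 4 young, 3 old) had 38 higher and 24 lower genes. The caspase gene Casp1 rose from 20.8 ± 6.91 to 83.4 ± 6.29 CPM (log2 1.99 ± 0.20, adjusted p = 0.000473). Gpha2 (chr 19, 6226380 to 6227768, log2 1.88 ± 0.15), Steap4 (2.14 ± 0.36) and the stefin genes Stfa3 (2.59 ± 0.29) and Cstdc5 (2.97 ± 0.41), near copies of uncertain count, rose. Itih5 (chr 2, 10153571 to 10256529) fell from 28.8 ± 4.72 to 9.76 ± 0.952 CPM (log2 -1.56 ± 0.23, adjusted p = 0.00437). Abi3bp (log2 -1.38 ± 0.24), Dlc1 (-1.28 ± 0.18), Clmn (-1.15 ± 0.22) and Tec (-1.12 ± 0.19) fell. Secreted inflammatory factors rose in 2 of 8, and 2 adjusted over the list alone (adjusted p = 0.0251, and 0.271 with an estimated correlation), namely Mmp3 and Il18, and keratinocyte markers in 1 and 4 of 6 (adjusted p = 0.0373 and 0.252), namely Krt14. Calls numbered 38, 37 and 38 without young replicates 1, 2 and 4, and 30, 94 and 38 without old replicates 1, 2 and 3. Steap4, Abi3bp, Clmn and Tec lost the call without some library (adjusted p up to 0.120).

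Cells labelled skin fibroblasts (n = 3 young, 3 old) had 0 genes past the threshold, and 336 of 11521 at an unadjusted edgeR p under 0.05. DESeq2 gave 5 and no filter 110. Without young replicate 3 the edgeR count was 2. The keratin gene Krt14 was at 8997 ± 2642 CPM in young and 10291 ± 1617 CPM in old animals (8165 in keratinocytes). Most often the keratinocyte list scored highest. The fibroblast markers ranked 5 to 9 of 23 types. Pdgfra (4.99), Col3a1 (563) and Dcn (1162 CPM) lay below muscle and thymic fibroblasts, and Col1a1 (867) between them.

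Satellite cells, the stem cells of muscle (n = 3 young, 3 old), had 33 higher and 26 lower genes. The DNA repair gene Xrcc6 rose from 14.98 ± 4.81 to 101 ± 28.9 CPM (log2 2.74 ± 0.31, adjusted p = 0.00376). Kng2 (chr 16, 22985854 to 23029482, log2 3.76 ± 0.53), Cyp26a1 (2.73 ± 0.41), Spock1 (3.09 ± 0.43) and Tmem229a (2.38 ± 0.45) rose. The transcription factor gene Sox11 fell from 351 ± 82.6 to 22.9 ± 1.52 CPM (log2 -3.93 ± 0.26, adjusted p = 1.45e-05). The chaperone gene Hyou1 (log2 -2.14 ± 0.23), Rsl24d1 (-2.17 ± 0.26), the collagen gene Col1a1 (chr 11, 94936224 to 94953042, -4.21 ± 0.83) and Olfm2 (-2.05 ± 0.38) fell. Imprinted growth genes fell in 1 of 11, and 6 adjusted over the list alone (adjusted p = 0.0417, and 0.206 with an estimated correlation), namely Plagl1. Calls numbered 98, 20 and 27 without young replicates 1, 2 and 3, and 13, 15 and 9 without old replicates 1, 2 and 3. Kng2, Cyp26a1, Tmem229a, Col1a1 and Olfm2 lost the call without some library (adjusted p up to 0.259), and Col1a1 was at -2.12 without young replicate 1.

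In muscle fibroblasts (n = 3 young, 3 old) the 1 gene past the threshold was Arhgef4 (chr 1, 34678188 to 34813309), which rose from 1.53 ± 0.665 to 48.5 ± 20.5 CPM (log2 5.08 ± 0.52, adjusted p = 0.000158), against 58 genes with DESeq2, 117 with no filter and 26 with the replicate block. Calls numbered 4 and 12 without old replicates 1 and 3.

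Lymph node endothelial cells (n = 3 young, 3 old) had 7 higher genes and 1 lower, against 122 genes with DESeq2, 336 with no filter and 0 with the replicate block. The cytokine gene Il6 rose from 8.96 ± 3.45 to 58.9 ± 23.1 CPM (log2 2.75 ± 0.34, adjusted p = 0.0275). Apold1 (log2 2.03 ± 0.24), the immediate-early genes Egr3 (chr 14, 70077203 to 70082614, 2.58 ± 0.30) and Arc (2.74 ± 0.40) and the apoptosis gene Pmaip1 (1.95 ± 0.26) rose. Vmn2r5 (chr 3, 64488609 to 64509842) fell from 21.4 ± 0.917 to 3.35 ± 1.11 CPM (log2 -2.67 ± 0.35, adjusted p = 0.0291). For AP-1 subunits, higher on balance, the risen genes were 0 of 10, and 6 adjusted over the list alone (adjusted p = 0.0218, and 0.112 with an estimated correlation). Calls numbered 0, 0 and 0 without young replicates 2, 3 and 4, and 17 without old replicate 3, and each of the 6 named genes lost the call without some library (adjusted p up to 0.324).

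Fibroblasts of the lymph nodes (n = 3 young, 3 old) had 15 higher and 19 lower genes, against 134 with DESeq2 and 310 with no filter. The cartilage collagen gene Col2a1 fell from 136 ± 52.7 to 26.6 ± 7.78 CPM (log2 -2.36 ± 0.31, adjusted p = 0.0158). Col9a1 (chr 1, 24177610 to 24252684, log2 -2.88 ± 0.29), Col9a3 (-2.26 ± 0.29), Col8a1 (-2.08 ± 0.28) and Cnmd (-2.19 ± 0.31) fell. Coch (chr 12, 51593341 to 51605771) rose from 82.5 ± 17.5 to 315 ± 91.9 CPM (log2 1.93 ± 0.25, adjusted p = 0.0153). Casp4 (log2 1.86 ± 0.29), Gldn (1.84 ± 0.26) and Stmn2 (54.6 to 155 CPM) rose. Complement genes rose in 3 of 13, and 10 adjusted over the list alone (adjusted p = 0.00793, and 0.112 with an estimated correlation), with C4b from 62.1 to 159 CPM, MHC class I genes in 1 and 9 of 14 (adjusted p = 0.00682 and 0.0919), namely Psmb8, and interferon-stimulated genes in 0 and 11 of 29 (adjusted p = 0.0263 and 0.159). Calls numbered 14 and 3 without young replicates 1 and 3, and 6 and 0 without old replicates 2 and 3, and each of the 4 named collagen genes, Cnmd, Coch, Casp4, Gldn and Stmn2 lost the call without some library (adjusted p up to 0.148).

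**Figure D4:**
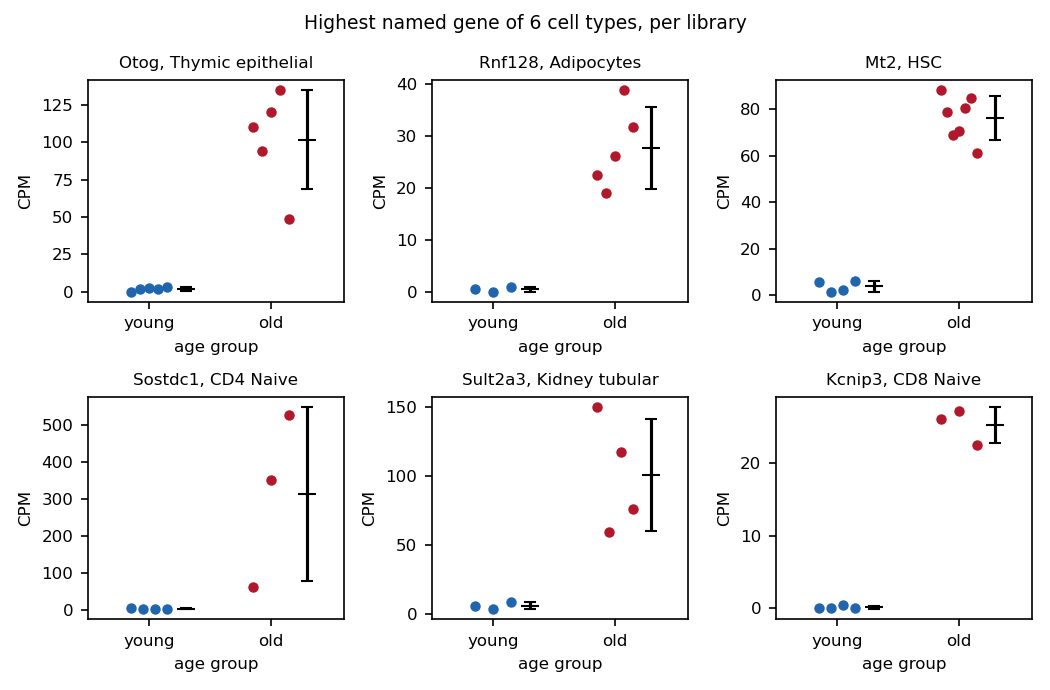
CPM per library on linear axes for the gene with the highest log2 fold change among the named genes of 6 cell types, with 1 point per library, young in blue and old in red, and the mean with a bar of 1 SD to each side. In each panel every old library lies above every young library, which the rule for named genes requires.

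The share of counts in immunoglobulin genes was 0.193% in young and 0.708% in old libraries, a difference of 0.515 ± 1.28 percentage points (SD over 23 cell types), and was higher in old animals in 21 of 23 (two-sided sign-flip permutation test, adjusted p = 6e-05, the smallest these permutations can give). CD4 naive old replicate 3 had 14.8% (the others 0.485% and 0.963%), CD8 memory old replicate 2 14.7% (0.615% and 3.57%) and virtual memory old replicate 4 6.31% (next 0.202%). Without each in turn, chosen after the results were seen, the difference in its cell type went from 5.15 to 0.454, from 3.72 to -0.480 and from 1.27 to 0.0353 points, and the overall mean was 0.311, 0.332 and 0.461. Without the CD8 memory library the call was lost (permutation adjusted p = 0.225). With medians over libraries, also chosen later, the mean was 0.170 (20 of 23, 6e-05), and on means per tissue 0.237 (0.00293). Total counts (0.447), genes with a count (0.447), ribosomal protein share (0.882), the share of the 10 top genes (0.882) and the median SD between libraries (0.904) did not pass the same permutation test.

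Between pairs of cell types, over 5214 genes, which are not independent replicates, the Spearman correlation of log2 fold changes averaged 0.137 ± 0.171 (SD) in 17 pairs from the same tissue and 0.0434 ± 0.111 in 236 other pairs, a difference of 0.0934 (one-sided permutation of tissue labels, p = 0.0059). Without the spleen T cell subsets, chosen after the results were seen, the difference was -0.00470 (permutation p = 0.538), so the higher correlation within a tissue rests on them.

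The Y-linked genes Ddx3y, Eif2s3y and Kdm5d summed to 18.8 to 179 CPM in 10 young libraries of 10 cell types and to at most 5.67 CPM in the other 160. In these 10 Xist, transcribed from an inactive X chromosome, was lower than the mean of the other young libraries of the cell type by a mean log2 ratio of -0.75 ± 0.52 (SD), in 10 of 10 (exact sign-flip p = 0.00195, the smallest it can give). They were replicate 3 of skin fibroblasts and replicate 1 of CD4 memory, HSC, kidney endothelial, kidney tubular, lymph node fibroblast, thymic fibroblast, muscle fibroblast, satellite and thymic epithelial cells.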

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

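The tests of memory-type cells as the only source, of shares from genes of T cells alone and of Y-linked libraries carrying the age calls, and the count of splits that part every replicate pair, were chosen after the results were seen.

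Chance singles out about 1 in 20 groups, and here it was 13 of 110 groups for library properties and 23 of 220 for named genes. In CD4 naive cells young replicate 1 had 0.30% immunoglobulin counts (nearest other 0.261%) and young replicate 2 9.14% ribosomal protein counts (10.6%). In CD4 memory cells young replicate 1 had 31347 genes with a count (22168) and old replicate 3 a total of 12734169 (3238467). Virtual memory young replicate 1 had a total of 6821886 (2838158) and old replicate 4 6.31% immunoglobulin counts (0.202%). The 10 top genes took 15.9% in kidney endothelial young replicate 1 (12.7%). Immunoglobulin counts were 0.0299% in brain endothelial old replicate 1 (0.0348%) and 0.813% in adipocyte old replicate 5 (0.138%). Thymic fibroblast young replicate 3 had 3.22% ribosomal protein counts (4.73%). Beta cell old replicate 2 had a total of 7278378 (1733379), 27590 genes (19537) and 42.8% in the 10 top genes (54.1%).

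Single libraries that stood apart in CPM of named genes were adipocyte old 5 for Atp6v0d2 (170.4) and old 2 for Mup9 (2.61), B cell young 1 for Lrg1 (4.01), and beta cell young 3 for Amy2a5 (2692), old 3 for Cabp2 (5.09) and old 2 for Gal (1.99). In CD4 memory cells they were old 5 for Arnt2 (46.9) and Cdk5r1 (66.8), young 3 for Eomes (29.6), and young 2 (66.5) and old 3 (8.01) for Clec10a. CD8 naive young 3 had 0.451 for Kcnip3, virtual memory old 4 had 5.38 for Slc28a2b, fat progenitor young 1 had 1.79 for Jchain and keratinocyte young 3 had 42.0 for Dlc1. Kidney endothelial young 1 had 70.8 for Agtr1a and young 3 had 327 for Myl9, and kidney tubular old 2 had 218 for Kap and 15.3 for C3 and old 1 had 45.7 for Lypd2. Thymic epithelial old 3 had 7.94 for Tmeff2, and thymic fibroblast young 2 had 47.9 for H19 and old 1 had 86.9 for Itm2a.

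The age change differed between memory and naive cells in 628 genes for CD4 and 371 for CD8. Of 100 exchanges of old and young within the CD4 subsets 5 gave as many genes, with 876 the highest other, so chance cannot be excluded. For CD8 1 of 100, the real one, did, but the highest other, 368, was within 1.5 times of it and the count was 225 without memory old replicate 3, so the margin over chance is narrow.

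T cell activation and exhaustion genes rose in old CD4 and CD8 naive cells, and memory cells in the sort may account for part. Genes of memory cells implied a share of such cells of 0.473 to 1.04 in old CD4 libraries. That from 1 naive gene minus it averaged 0.244. For CD8 the shares (0.0540 to 0.128) and these differences (-0.0353 and -0.0676 with memory and virtual memory cells as the source) decide nothing, since 120 of 194 and 30 of 73 memory genes, among them S100a8, Lyz2 and Jchain, and 35 of 38 and 46 of 46 naive genes, most often adipocyte genes, were highest outside T cells or on lists of other cells, as were 27 of 44 and the 1 naive gene for CD4. From genes 8-fold higher in a T cell subset than in other sorted types and on none of those lists, library medians were 0.501 to 0.751 for CD4 (9 genes) and for CD8 0.208 to 0.445 with memory (22 genes, from -0.0282 to 2.04) and 0.0659 to 0.202 with virtual memory cells (16 genes, from -0.0275 to 1.09), and 0 naive genes were left. Of risen genes 1.68% (14 of 833) in CD4 and 9.92% (59 of 595) in CD8 lay in every old library above every memory-type library. By means 53.8% (448) and 43.7% (260) did. No mixture exceeds its source, so the 59 argue against sorted memory cells as theirs alone. These cells stay open for the rest and for CD4, as do, untested, other memory cells and an age change of naive cells.

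Immunoglobulin transcripts were higher in old libraries outside B cells (log2 ratio 1.87, 20 of 22 cell types, permutation p = 2e-05). Plasma cells or their RNA in the sorted samples may be a source, since Jchain, Mzb1 and Derl3 together rose by 0.957 (18 of 22, permutation p = 0.00204, adjusted 0.00408), though Mzb1 alone had 0.03 (9 of 15, p = 0.914). The B cell list had 0.443 (16 of 22, permutation p = 0.0492, adjusted 0.0591), so B cells stay open beside them. More plasma cells in old tissue stays open and was not tested.

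Y-linked transcripts in 10 young libraries are consistent with male animals among those pooled, since Xist was lower in 10 of 10 (mean log2 ratio -0.746, exact sign-flip p = 0.00195). A shared batch stays open, as 0.137 of random picks of 1 young library per cell type had deviations as alike. Whether these libraries carry the age calls stays open, with a median ratio of counts of 0.966 (0.437 to 4.17).

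With other splits of the libraries, chance can be excluded for 13 cell types in which 1 split, the real one, gave as many genes. Real and highest other counts were 1397 and 1 in adipocytes (56 splits), 373 and 128 in B cells (100), 183 and 4 in beta cells (35), 325 and 20 in CD4 memory (100), 1135 and 0 in CD4 naive (35), 922 and 78 in CD8 naive (35), 397 and 9 in virtual memory cells (100), 69 and 10 in fat progenitors (35), 1199 and 8 in HSC (100), 62 and 2 in keratinocytes (35), 1039 and 74 in kidney tubular (35), 1531 and 1 in thymic epithelial cells (100) and 235 and 1 in thymic fibroblasts (35). For the shared change 1 of 40 exchanges did, with 2033 and 49. In kidney endothelial cells 1 of 35 did, with 176 and, where young replicate 1 with its Y-linked counts joined the old, 137, so the margin over chance is narrow there too (55 without old replicate 2). In brain endothelial cells 2 of 35 splits did, with 87 and 114, so over all splits chance cannot be excluded. The split with 114 set replicates 3 and 4 of both ages against the rest and so follows the replicate numbers, which pair these libraries. Of the 8 splits that part all 3 pairs 1, the real one, gave as many, with 1 the highest other. Such splits are too few for a share under 0.05. Splits were too few, at 10, in CD8 memory cells (117 and 0), liver progenitors (95 and 1), lymph node endothelial cells (8 and 2) and fibroblasts (34 and 3), muscle fibroblasts (1 and 0), satellite cells (59 and 0) and skin fibroblasts (0 and 2).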

How the results depend on the processing

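The alternatives without libraries with Y-linked counts, without the spleen T cell subsets, of the immunoglobulin share, with limma on genes missing in some cell types and those of the marker lists were chosen after the results were seen. With RLE size factors each of 30 counts stayed within 1.5 times, and 1 named result reversed under the alternatives run. That was the difference in correlation between pairs of the same and of other tissues, at -0.00470 without the spleen T cell subsets (permutation p = 0.538), which leaves fewer pairs. Among genes not named 1 called in HSC changed sign without young replicate 3. Of the genes called within cell types 98.5% kept call and sign with RLE, 89.4% with no filter, 97.8% with DESeq2 and 64.3% with the replicate block. Of named genes tested, 4 lost the call with DESeq2, 1 with RLE, 0 with no filter and 34 with the block. Small changes were often missed, since 6.32% of simulated 2-fold changes were recovered in neurons, 13.9% in CD4 naive cells and 49.4% in liver progenitors, and depth was not tested apart from spread and library number.

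DESeq2 called 953 genes for the CD4 and 623 for the CD8 interaction, 262 in brain endothelial, 567 in CD4 memory, 574 in CD8 memory and 647 in virtual memory cells, 152 in fat progenitors, 127 in keratinocytes, 122 in lymph node endothelial cells and 134 in fibroblasts, 58 in muscle fibroblasts, 378 in neurons, 215 in satellite cells, 5 in skin fibroblasts and 376 in thymic fibroblasts. Without the low-count filter the counts were 1007 and 871 for the CD4 and CD8 interactions, 670 in B cells, 419 in beta cells, 437 in brain endothelial, 839 in CD4 memory, 1923 in CD4 naive, 1026 in CD8 memory and 900 in virtual memory cells, 314 in fat progenitors, 374 in keratinocytes, 363 in kidney endothelial and 1738 in kidney tubular cells, 209 in liver progenitors, 336 in lymph node endothelial cells and 310 in fibroblasts, 117 in muscle fibroblasts, 1192 in neurons, 412 in satellite cells, 110 in skin and 508 in thymic fibroblasts, with 43 gene list and 4 marker list calls. The cause was not tested.

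In brain endothelial cells, taken as paired, the replicate block gave 212 genes. Elsewhere libraries share only a number, and the block gave 240 in B cells, 12 in CD8 memory cells, 7 in fat progenitors, 602 in HSC, 406 in kidney tubular cells, 0 in lymph node endothelial cells, 26 in muscle and 143 in thymic fibroblasts, 1012 for the shared change, 11 gene list and 0 marker list calls. For neurons no paired analysis was possible, as the ages shared 1 number. An estimated correlation left 6 gene list and 0 marker list calls. Limma on fold changes called 76 shared genes over cell types and 22 over tissues, and with genes missing in some cell types 107 and 32, from fewer values than libraries. Without libraries with Y-linked counts there were 168 genes in CD4 memory cells, 762 in HSC, 378 in kidney endothelial and 349 in kidney tubular cells, 14 in lymph node fibroblasts, 98 in satellite cells and 2 in skin fibroblasts.

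Leaving out each library gave 457 to 2001 genes in adipocytes, 288 to 478 in B cells, 144 to 251 in beta cells, 22 to 137 in brain endothelial, 133 to 358 in CD4 memory, 692 to 1909 in CD4 naive, 3 to 878 in CD8 memory, 593 to 859 in CD8 naive and 269 to 432 in virtual memory cells, 24 to 227 in fat progenitors, 701 to 1484 in HSC, 30 to 94 in keratinocytes, 55 to 378 in kidney endothelial and 349 to 994 in kidney tubular cells, 50 to 96 in liver progenitors, 0 to 17 in lymph node endothelial cells and 0 to 36 in fibroblasts, 1 to 12 in muscle fibroblasts, 2 to 679 in neurons, 9 to 98 in satellite cells, 0 to 2 in skin fibroblasts, 1220 to 1497 in thymic epithelial cells and 136 to 241 in thymic fibroblasts. It gave 258 to 1176 and 225 to 986 for the CD4 and CD8 interactions and 60 to 84 gene list and 16 to 33 marker list calls within cell types. Leaving out each cell type gave 1586 to 2156 shared genes, 7 to 11 lists and 1 library property.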

Other observations

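Marker lists of the sorted types were scored in each library as the mean of log2 CPM centred over cell types, a comparison of different genes noticed after the levels were seen. Fat progenitors and lymph node, muscle and thymic fibroblasts scored most often highest on the skin fibroblast list, skin fibroblasts and thymic epithelial cells on the keratinocyte list, lymph node endothelial cells on the kidney endothelial list and virtual memory cells on the CD8 memory list. Some of their own markers had a higher mean there than in any other sorted type, namely Dpp4, Pi16, Cd34 and Ly6a in fat progenitors, Pdgfra and Gsn in muscle fibroblasts, Col1a1 and Col3a1 in lymph node fibroblasts, Foxn1, Psmb11 and Aire in thymic epithelial cells, Lyve1, Cdh5, Egfl7 and Pecam1 in lymph node endothelial cells and Cd3e and Il2rb in virtual memory cells. In skin and thymic fibroblasts 0 did. No explanation was tested.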
